A study of Mus musculus with 2 samples.

How the data were processed

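Bone marrow cells of 1 T2D library and 1 control library were analysed, each from a group of 3 mice per the labels' protocols. The labels do not state in full whether cells of the 3 mice were pooled before loading. The deposited matrices hold raw UMI counts per gene and barcode, per the file headers, for 32285 genes and every detected barcode, 1738949 in T2D and 2109676 in control. Reads were aligned and counted by the authors with Cell Ranger against mm10. The version was 2.1.1 per the submitters' processing notes and 4 per the file headers, and which made these counts was not checked. The labels' protocols name the single cell 3' v2 kit as the library chemistry. Whether the deposited barcodes are those of that kit was not checked, so the chemistry is left open. No normalization of these counts was recorded in a header or label, and the values are whole numbers.

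The authors' own choice of cells was not used here, so cells were called from the counts. The minimum was the larger of 500 UMIs and the steepest point of either barcode-rank curve between 100 and 3000 UMIs. The steepest points were 1012 UMIs in T2D and 2191 UMIs in control, so 2191 UMIs was applied to both libraries, leaving 7435 and 6255 barcodes. A minimum of 200 genes left 7433 and 6253, and a maximum of 10% mitochondrial counts left 7321 and 6213. Scrublet in scanpy, with an expected rate of 0.8% per 1000 cells, marked 170 and 117 doublets, which were removed. Called cells held 57398304 UMIs in T2D and 72086425 in control, 75.5% and 82.9% of each library.

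Counts were scaled to 10000 per cell and log-transformed. From genes detected in at least 10 cells, 2000 variable genes were chosen per library and combined, without immunoglobulin and T cell receptor variable segments and sex-linked genes. The neighbour graph used 30 principal components and 15 neighbours, and Leiden clustering had a resolution of 1, over both libraries together with no integration. Clusters were named from 20 marker lists fixed before the data were examined, requiring at least 3 markers that were 2-fold above other cells and detected in 10% of the cluster. Monocyte clusters with a mean cell cycle log2 fold above 0 were kept apart as cycling monocytes, a limit set after the data were seen, and cluster 11 and the S-phase cluster 4 stayed unnamed. Cluster 17 scored as B cells but was led by more B progenitor markers, so B lineage cells were compared as a whole or by cluster number.

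For classes with at least 100 cells per library, counts were summed per library and class and given as CPM of the class total with exact Poisson intervals. Log2 ratios have exact conditional binomial intervals, and shares have Clopper-Pearson intervals, all at 95%. With 1 library per group no test between groups was made and no p-value is given. A gene was measured with at least 50 summed counts in 1 library (20 for lists in classes under 500 cells in either library). The floor was 3 counts, and no fold is given where both libraries were at or under it. For 31 gene lists fixed beforehand, the median log2 ratio of at least 5 measured genes, with a prior of 0.5 counts, was set against 10000 random lists matched in 20 bins of mean expression. Free RNA was the summed profile of barcodes below 100 UMIs.

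Genes were named by a rule fixed before the data were examined. It took genes with at least 50 CPM in 1 library, a level in the higher library at or above that library's free RNA, and an interval bound of at least 1.5-fold, ranked by that bound. The 12 highest and 12 lowest were taken in monocytes and neutrophils, and 8 and 8 in B lineage cells, T cells and all cells. Unnamed transcripts and mitochondrial, ribosomal, haemoglobin, antigen receptor segment and sex-linked genes were left out. The 2 highest and 2 lowest members of a list could be named as its examples, as could preset genes for osteoclast formation, inflammation and sex. The other genes in the account of mature osteoclast and macrophage transcripts, the S100a8 and Cd79a levels beside free RNA, and the values of named genes in parts of the B lineage and neutrophils, were chosen after their values were seen. Some genes that met the rule are not described. Coordinates are 1-based, from GENCODE vM21 on GRCm38 (mm10), matched by gene ID.

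Alternatives tried were minimums of 1000 and 500 UMIs, the Cell Ranger 2 cutoff, mitochondrial maximums of 5% and 20%, no doublet removal, resolutions of 0.5 and 2, separate clustering, thinning to 500 UMIs before clustering, another denominator, TMM and median ratio scaling, a minimum of 10 summed counts, cells weighted equally, subtraction of free RNA, 10 bins, free RNA from barcodes below 50 UMIs and thinning to 1000 UMIs. The minimum of 500 UMIs, the counting of cluster 11 with monocytes and the S100a8 and S100a9 shares of free RNA were added after seeing the data.

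The ratios, intervals and list percentiles were tested on simulated class sums with 200 changed genes. Both simulated libraries were drawn from the control library's means with counting error only. Cell calling, clustering, free RNA and the spread between cells or mice were not simulated, so the rates below hold for counting error alone. In monocytes, over 8163 genes, 99% of genes changed 2-fold and 98% of those changed 3-fold were recovered, and 95.5% of intervals covered the true value. In neutrophils, over 8574 genes, 100% and 99% were recovered, in B lineage cells, over 8095 genes, 96% and 98%, and in T cells, over 2771 genes, 46% and 92%. Among unchanged genes, 2 passed the fold and level limits of the naming rule in T cells and 0 in the other classes. Software was python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9 and edgeR 4.0.16 in R 4.3.3, the last for TMM factors only.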

Results

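Whole bone marrow from the femur and tibia of C57BL/6J mice aged 7 months was profiled by droplet-based single-cell RNA sequencing (10x Genomics, 3' end counting with unique molecular identifiers, UMIs). The type 2 diabetes (T2D) group had received a high-fat diet and a single intraperitoneal injection of 100 mg/kg streptozotocin, a compound toxic to pancreatic beta cells. Each group had 3 mice per the labels and is represented by 1 library. The T2D matrix held 76021490 UMIs and the control matrix 86929475. After cell calling at a minimum of 2191 UMIs, 7151 T2D cells and 6096 control cells remained, with medians of 5925 and 9424 UMIs and of 1595 and 2074 genes per cell. With 1 library per group there was no replicate check, so each difference below is between these libraries. Intervals are 95% and cover counting error only. Log2 ratios are T2D over control.

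The labels give the bone immune microenvironment as the subject, so cell composition was compared between the libraries. Neutrophils, the most abundant class at the main settings, made up 28.6% of T2D cells (exact binomial interval 27.5 to 29.6) and 37.2% of control cells (36.0 to 38.4). With a minimum of 1000 UMIs, B lineage cells were more abundant than neutrophils in T2D, at 29.1% against 26.1%. Monocytes taken with cycling monocytes were 28.2% of T2D cells at the main settings. At other cell calling and clustering settings they exceeded neutrophils in T2D, as with 31.7% against 28.6% at resolution 0.5. The exceptions were resolution 2 (28.2% against 28.6%) and separate clustering (15.3% against 28.5%). Mature neutrophils were 6.32% (5.77 to 6.91) in T2D and 14.0% (13.1 to 14.9) in control, and immature neutrophils, which carry secondary granule transcripts, 22.2% and 23.2%, a division that changed with the settings, as given below. B lineage cells were 23.5% (22.6 to 24.5) of T2D cells and 14.7% (13.8 to 15.6) of control cells. Their parts are given as numbered clusters, because cluster 17 had more B progenitor markers (3) than B cell markers (0) among its 10 leading genes. Clusters 2, 3 and 17, closest to B cells over all markers, were 9.90% against 3.84%, 6.70% against 4.41% and 2.99% against 3.89%, and the B progenitor clusters 13 and 15 were 2.55% against 1.38% and 1.40% against 1.18%. Dendritic cells were 4.50% against 8.02%, T cells 1.75% against 3.02%, and granulocyte-monocyte progenitors 3.31% against 4.74%. Stem and progenitor cells were 0.671% of T2D cells and 1.49% of control cells.

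Monocytes outside the cell cycle made up 15.1% of T2D cells and 13.8% of control cells. Monocytes in clusters 5 and 6, which carried cell cycle transcripts above the mean of all cells, a limit set after the data were seen, were 13.1% and 8.84%. Natural killer cells were 1.12% and 1.23%, and basophils with mast cells 1.10% and 2.15%. Clusters without a class name held 7.20% of T2D cells and 4.81% of control cells. One of these, cluster 11, was led by Ace, Treml4 and Fcgr4 and held 226 T2D cells (3.16%) and 18 control cells (0.295%). It missed the marker criteria of every class. The monocyte shares above and the monocyte values below leave it out, except where its inclusion is stated, so the monocyte class may be incomplete. A cluster mostly from 1 library may be that library. In the main clustering no cluster met the criteria for macrophages, osteoclasts, erythroid cells, megakaryocytes, plasma cells, eosinophils, stromal or endothelial cells. Other settings gave an erythroid cluster (12 T2D and 4 control cells at 1000 UMIs, 14 and 6 at 500 UMIs) and a plasma cell cluster (8 and 5 at the Cell Ranger 2 cutoff).

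These shares hold for cells with at least 2191 UMIs, at least 200 genes and at most 10% mitochondrial counts, after Scrublet had removed 170 T2D and 117 control doublets, in libraries whose median UMIs per cell differed 1.59-fold. B lineage cells lay close to the minimum, with medians of 2987 and 3541 UMIs. The log2 ratio of the mature neutrophil share, -1.14, depended on the settings: it was -0.57 at 1000 UMIs, -0.43 at a clustering resolution of 2 and -0.56 after thinning to 500 UMIs. The mature part of the neutrophil gap therefore also depended on them: at 1000 UMIs mature neutrophils were 6.67% and 9.92%, beside 26.1% and 35.1% for all neutrophils. That of granulocyte-monocyte progenitors, -0.52, was -1.42 at 1000 UMIs and -1.66 at 500 UMIs, and turned to 0.29 at resolution 2 and 0.43 with each library clustered on its own, where that of all monocytes turned from 0.32 to -0.97.

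**Figure D1:**
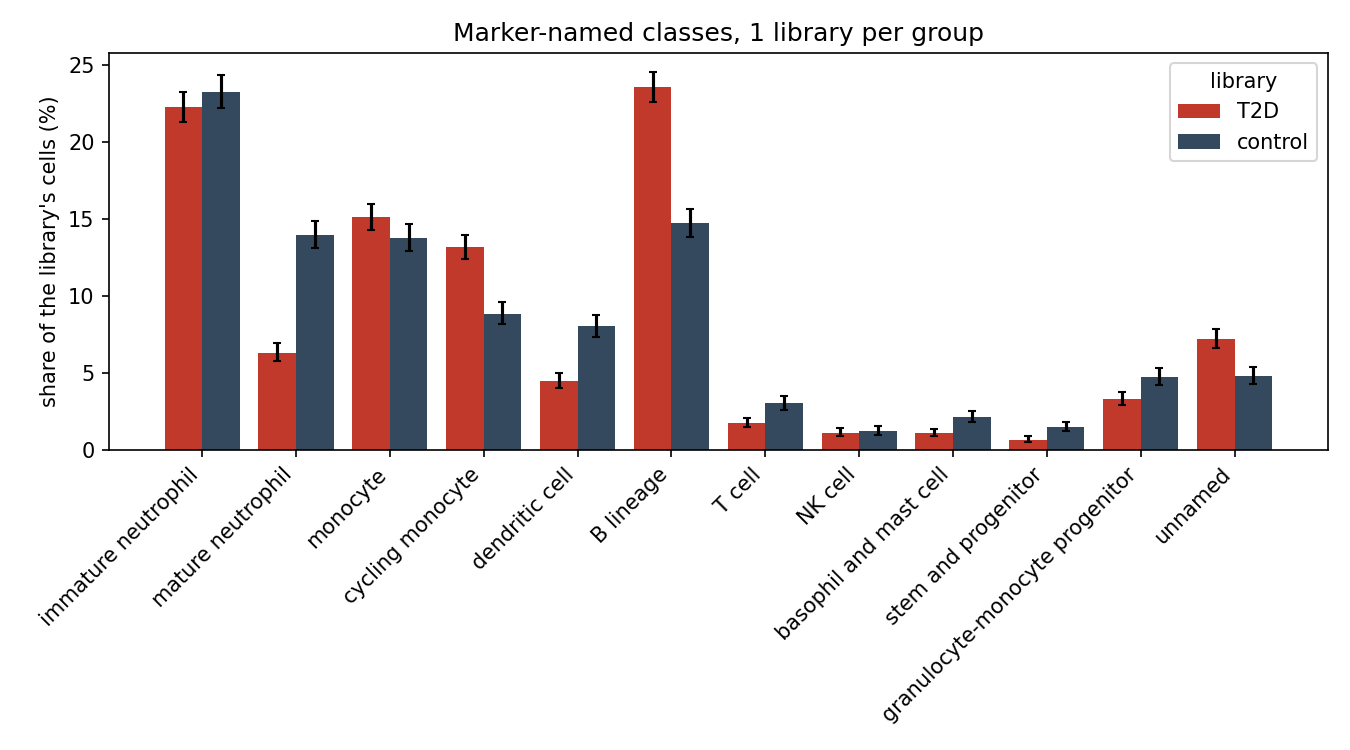
Share of called cells (percent, vertical axis) per cell class in the T2D and control libraries (1 library each), with 95% exact binomial intervals that cover counting error only. B lineage cells were 23.5% of T2D and 14.7% of control cells, and mature neutrophils 6.32% and 14.0%.

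Monocytes were compared because they include the precursors of osteoclasts. Here 1079 T2D cells, 1053 of them in cluster 10, were set against 840 control cells, 814 of them in cluster 12. Lpl (ENSMUSG00000015568, chromosome 8, 68880491 to 68907448), which encodes lipoprotein lipase, was 14.6-fold lower in the T2D library, at 18.0 against 263 CPM, the gene's counts relative to all UMIs of the class (log2 ratio -3.87, interval -4.12 to -3.63). The chemokine genes Ccl3 (ENSMUSG00000000982, chromosome 11, 83647844 to 83649355) and Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453) were 8.28-fold and 6.31-fold lower. Vcan (ENSMUSG00000021614, chromosome 13, 89655312 to 89742509), which encodes the matrix proteoglycan versican, was 3.13-fold higher at 775 against 247 CPM. Plin2 (ENSMUSG00000028494, chromosome 4, 86648386 to 86670060), which encodes a lipid droplet coat protein, was 3.47-fold higher at 424 against 122 CPM.

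Other genes higher in T2D monocytes included Bst1, an ADP-ribosyl cyclase gene, at 5.03-fold, Fkbp5, a glucocorticoid-inducible co-chaperone gene, at 4.26-fold, Pla2g7, which encodes platelet-activating factor acetylhydrolase, at 4.18-fold, and Thbs1, which encodes thrombospondin 1, at 3.68-fold. Gcnt2 and Atp11a were 4.32-fold and 3.91-fold higher. The Fc receptor gene Fcgr4 was 7.84-fold higher, with a log2 ratio of 2.97 that became 3.64 with cluster 11 counted among the monocytes, a setting chosen after seeing the data. The acute-phase gene Saa3 was 10.6-fold higher at 78.6 against 7.39 CPM, but 10 cells held 41.1% of its T2D counts and 91.9% of its control counts. Acot1, an acyl-CoA thioesterase gene that was 6.65-fold higher, has close paralogs with which reads may have been shared. Lower in T2D monocytes were the transcription factor genes Atf3 at 4.67-fold, Klf4 at 2.78-fold and Jun at 2.40-fold, the phosphatase gene Dusp1 at 2.34-fold, the fractalkine receptor gene Cx3cr1 at 2.33-fold, the fatty acid binding protein gene Fabp5 at 2.74-fold and the prostaglandin dehydrogenase gene Hpgd at 3.40-fold. Stxbp6 and AI839979 were 3.20-fold and 2.29-fold lower. All of these monocytes lay in clusters with over 90% of their cells from 1 library, a share of monocytes that was 89.4% with cells thinned to 2191 UMIs and 0.417% at 500 UMIs.

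**Figure D2:**
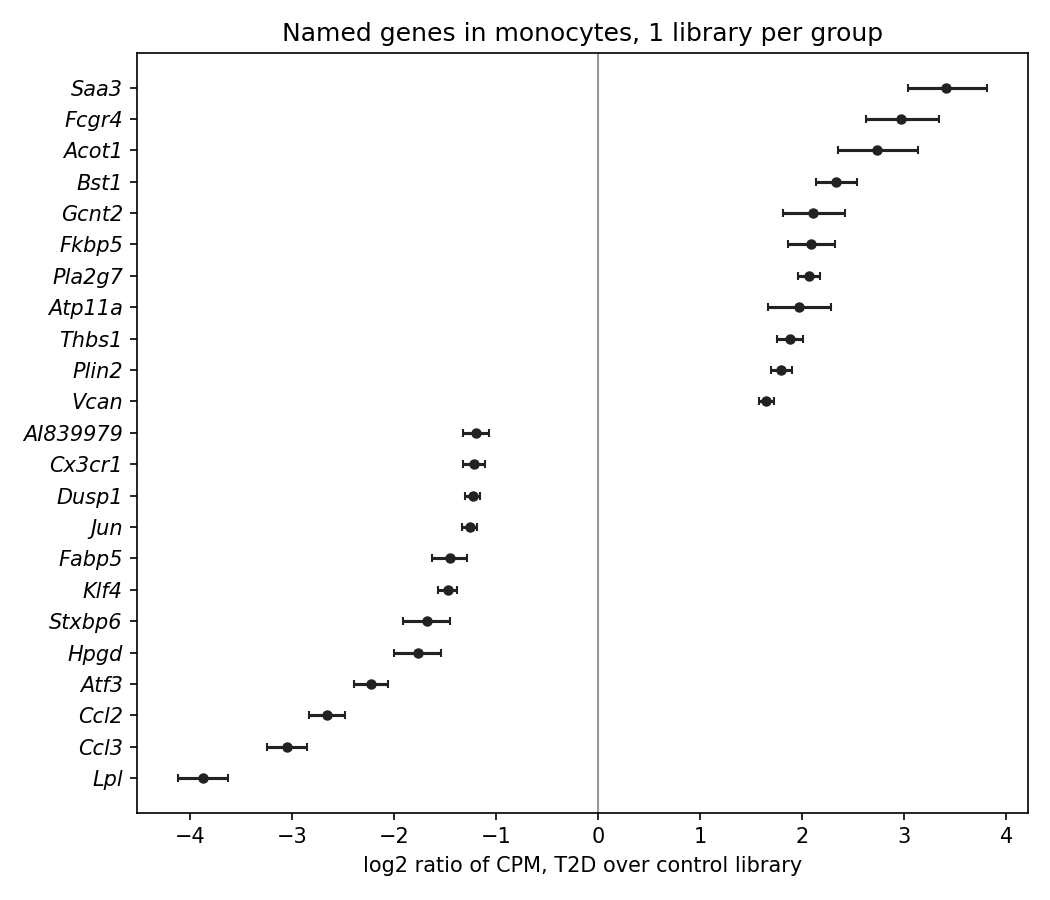
Log2 ratio of CPM, T2D over control (horizontal axis), of genes named by rule in monocytes, 1 library per group, with 95% exact intervals for counting error. The genes ran from Lpl at -3.87 to Saa3 at 3.41.

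Gene lists fixed before the data were examined were read as the median log2 ratio of their measured members, with the percentile of that median among 10000 random lists of matched expression, as a description of these libraries. In monocytes the immediate early and stress list had a median of -0.54 (percentile 0), with 16 of 18 members lower in T2D. Atf3 (log2 ratio -2.22) and Jun (-1.26) were the lowest, while Hspa8 (0.43) and Egr1 (0.69) were higher. The list of inflammatory cytokines and NF-kB targets had a median of -0.57 (percentile 0), with 20 of 23 members lower, among them Cxcl10 at 0.846 against 14.4 CPM and Ccl3 at 29.6 against 245 CPM. Nfkbia, which encodes an inhibitor of NF-kB, and Icam1 were higher, with log2 ratios of 0.48 and 0.62. Each group was 1 library, so handling of the library and group were the same split. The control level of Ccl3 equalled that of the control library's free RNA, 245 CPM, and free RNA Ccl3 was also lower in T2D, at 73.1 CPM. A level at or below that of free RNA does not by itself mean that it came from free RNA. In lymphoid cells of the control library the share of free RNA was estimated at 1.82% to 9.57% of UMIs.

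The type I interferon response list lay the other way in monocytes, with a median of 0.62 (percentile 100) and 30 of 37 members higher in T2D. Rtp4 (30.3 against 10.1 CPM) and Oas2 (18.4 against 6.43 CPM) were the highest, and Ifitm3 (log2 ratio -0.38) and Ifit3 (-0.81) were lower. Other members were near 0: Ifit1 at -0.06 (-0.48 to 0.35), Rsad2 at 0.10 (-0.33 to 0.52) and Usp18 at -0.01 (-0.42 to 0.41). All 6 measured MHC class II genes were lower in T2D monocytes, with a median of -0.97 (percentile 0); H2-Ab1 was 33.8 against 78.0 CPM and Cd74 116 against 248 CPM. This median was -0.30 with doublets kept and -0.22 at a minimum of 500 UMIs, the latter chosen after seeing the data. Unfolded protein response genes had a median of 0.21 (percentile 100), with Pdia4 and Calr higher at log2 ratios of 0.83 and 0.47. Lipid handling genes went both ways around a median of -0.20 (percentile 5.54): Plin2 and Angptl4 were higher, Lpl and the sterol synthesis gene Sqle lower.

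The title of the series names decreased osteoclast differentiation. The osteoclast differentiation list had a median log2 ratio of -0.08 in monocytes (percentile 56.8), beside -0.08 for all 8281 genes measured there, and one of 0.01 under TMM scaling. Of its 37 measured members 14 were higher and 23 lower in T2D. Jdp2, which encodes a transcription factor that takes part in osteoclast formation, was higher at 17.5 against 9.53 CPM, as was the adaptor gene Gab2 at 36.9 against 21.7 CPM. Itgb3, which encodes integrin beta 3, was lower at 2.30 against 9.77 CPM, below its free RNA levels of 7.26 and 16.6 CPM, and Fos was lower at a log2 ratio of -0.64 (-0.68 to -0.60). Tnfrsf11a, the gene for the RANKL receptor RANK, had 40 counts in T2D and 46 in control, a log2 ratio of -0.18 (-0.83 to 0.46), so no difference was detectable at this depth. Csf1r, the gene for the M-CSF receptor, had a log2 ratio of -0.32 (-0.40 to -0.24), and Nfatc1, the gene for the main osteoclast transcription factor, one of -0.04 (-0.27 to 0.20).

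Acp5, the gene for tartrate-resistant acid phosphatase, was higher in T2D monocytes at 15.2 against 8.82 CPM (log2 ratio 0.79, 0.36 to 1.22), below its free RNA levels of 26.2 and 20.1 CPM. Ctsk, the cathepsin K gene, had 3 counts in each library. Mmp9 had a log2 ratio of -0.34 (-0.75 to 0.07), far below its free RNA level, which turned to 0.29 once free RNA was subtracted and was -1.01 at a minimum of 500 UMIs. Irf8, a repressor of osteoclast formation, was lower at a log2 ratio of -0.23 (-0.31 to -0.15), at 269 and 316 CPM, below its free RNA levels of 314 and 332 CPM. The list of negative regulators had a median of -0.23 (percentile 3.51), inside the central 95% of random lists, with Pirb (0.65) higher and Tnfaip3 (-1.90) lower. The cytokine gene Tnf had 15 counts in T2D and 93 in control, a log2 ratio of -2.61 (-3.51 to -1.82), at levels of 1.81 and 11.1 CPM that lay below its free RNA levels of 7.59 and 30.4 CPM, themselves lower in T2D. Il1b, also below its free RNA levels of 29.2 and 35.7 CPM, had a log2 ratio of -0.05 (-0.58 to 0.48), which was -1.24 at 1000 UMIs, -1.50 with each library clustered on its own and 0.66 with cluster 11 included.

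**Figure D3:**
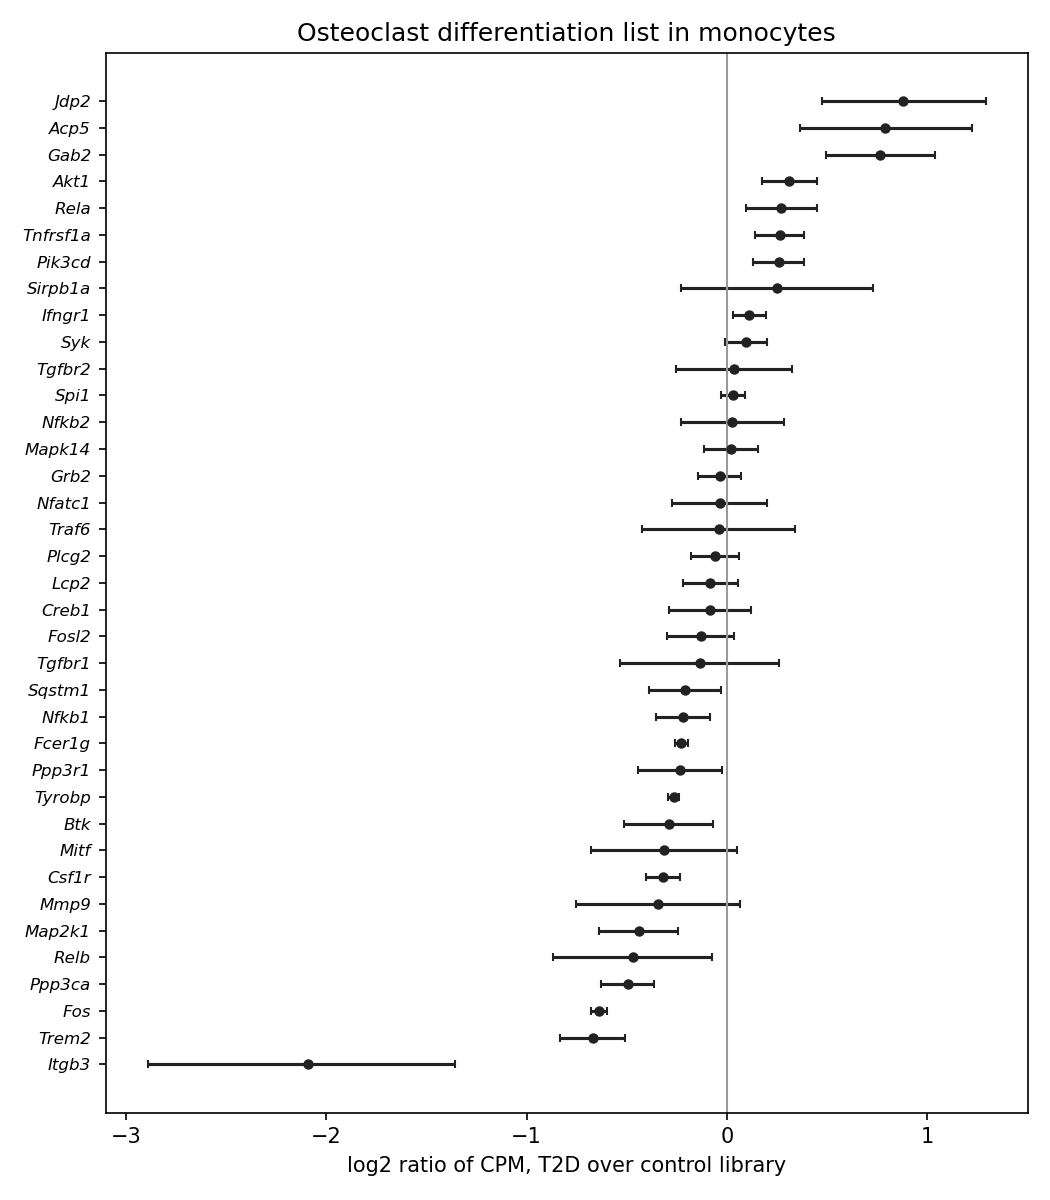
Log2 ratio T2D over control (horizontal axis) of the 37 measured genes of the osteoclast differentiation list in monocytes, 1 library per group, with 95% exact intervals for counting error. Members lay on both sides of 0, from Itgb3 at -2.09 to Jdp2 at 0.88.

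Neutrophils were compared over 2043 T2D and 2269 control cells. Values over all neutrophils mix classes whose shares differ, since mature neutrophils held 15.3% of neutrophil UMIs in T2D and 27.2% in control. Each part also pools clusters whose shares differ. Among immature neutrophils, clusters 21 and 22, both led by Fcnb, held 200 and 149 T2D cells against 210 and 215 control cells. Clusters 0 and 1 held 574 and 668 against 410 and 582. Among mature ones, cluster 7, led by Retnlg and Mmp8, held 143 against 475 cells, and cluster 8 held 309 against 377. Acot1 (ENSMUSG00000072949, chromosome 12, 84009490 to 84018371) was 19.2-fold higher in T2D at 99.7 against 5.20 CPM (log2 ratio 4.26, interval 3.99 to 4.54), with the paralog limit given above. Mir142hg, the host gene of microRNA 142, was 5.53-fold higher. The cystine transporter gene Slc7a11 (ENSMUSG00000027737, chromosome 3, 49892526 to 50443614) was 2.33-fold lower at 73.7 against 172 CPM, with log2 ratios of -1.69 in immature and -0.23 in mature neutrophils. Pira2 was 2.73-fold and Oas3 2.15-fold higher, both members of gene families whose reads could be split between copies. The protease gene Asprv1 was 2.64-fold, the granule gene Olfm4 2.03-fold and the ferritinophagy receptor gene Ncoa4 1.84-fold higher. Fmnl2, Ap2a2, Cstdc4, Hist1h1e and Acvrl1 were 2.07-fold, 2.04-fold, 1.97-fold, 1.95-fold and 1.90-fold higher. Some of these pooled values lay below those of both parts. Cstdc4 had log2 ratios of 2.71 in immature and 1.63 in mature neutrophils, beside 0.98 over both, and Asprv1 2.08 and 1.84 beside 1.40. Ap2a2 had 0.995 in immature neutrophils but 0.17 (-0.20 to 0.52) in mature ones. The other genes named as higher in neutrophils had intervals above 0 in both parts.

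Only 9 genes met the naming rule on the lower side in neutrophils. Beside Slc7a11 they included Gadd45a at 2.20-fold, Dnajb9 at 1.94-fold, Dusp6 at 1.90-fold, Ifitm6 at 1.73-fold, Rgs2 at 1.73-fold and Mpc2 at 1.63-fold. The interferon list had a median of 0.93 (percentile 100), with 30 of 33 members higher, among them Oasl1 at 4.45 against 0.512 CPM and Rtp4 at 24.7 against 5.12 CPM, while Ly6c2 and Ifitm3 were lower. The immediate early list had a median of -0.47 (percentile 0), with Jun at 92.2 against 319 CPM. In immature neutrophils alone that list's median was -0.28 (percentile 0.64) and in mature ones -0.03 (percentile 30.1). The inflammatory list had a median of -0.54 (percentile 0), with Ccl3 and Ptgs2 lower and Nfkbia and Ccl6 higher, but -0.30 in immature neutrophils (8 higher, 10 lower) and -0.18 in mature ones (10 higher, 13 lower), each smaller than over the mixed class. Ccl3, at 7.08 against 36.6 CPM, lay far below its free RNA levels of 73.1 and 245 CPM, which were also lower in T2D.

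Primary granule genes had a median of -0.48 in neutrophils (percentile 0): Elane, the neutrophil elastase gene, was 144 against 244 CPM and Ms4a3 40.1 against 71.3 CPM. That median was -0.66 in immature neutrophils (percentile 0) and -0.12 in mature ones (percentile 37.0). The Fcnb-led clusters 21 and 22 were a smaller part of immature neutrophils in T2D than in control. The list was not compared within clusters, so the value may reflect this mix. Secondary and tertiary granule genes had medians of opposite sign in the parts, beside 0.00 over both. The median was 0.17 in immature neutrophils (percentile 97.8, 9 higher and 6 lower) and -0.19 in mature ones (percentile 0.55, 12 of 15 lower). Mature neutrophils mix clusters 7 and 8 in unlike shares, and cluster 7 is led by Mmp8 and Mmp9 among others. Values within these clusters were not computed. Genes for oxidative phosphorylation encoded in the nucleus had a median of -0.33 (percentile 0), with 80 of 84 lower, including Ndufa4 at 89.7 against 152 CPM. The 13 genes of the mitochondrial genome were all higher, with a median of 0.42 (percentile 100). Among lipid genes, Plin2 (139 against 39.9 CPM) and Apoe (25.1 against 6.82 CPM) were higher, and Sqle (0.412 against 4.56 CPM) lower, around a median of -0.11 (-0.04 in immature and -0.35 in mature neutrophils).

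B lineage cells were compared over 1683 T2D and 896 control cells. Their values also mix stages, with 32.8% of B lineage UMIs in clusters 13 and 15 in T2D and 41.0% in control. Values over clusters 2, 3 and 17 are not free of such a mix. Cluster 17, led by B progenitor markers, held 214 T2D and 237 control cells. Cluster 2 held 708 and 234, and cluster 3 held 479 and 269. Ly6a (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031), an interferon-inducible surface protein gene, was 3.63-fold higher in T2D at 314 against 86.4 CPM (log2 ratio 1.86, interval 1.71 to 2.02). Ptpn22, the gene of a phosphatase that restrains antigen receptor signalling, was 4.47-fold higher. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, was 2.49-fold, Ddit4 2.56-fold, Ifi27l2a 2.39-fold, Ppp1r21 2.95-fold and Gimap3 2.20-fold higher. Cd24a (ENSMUSG00000047139, chromosome 10, 43578284 to 43584265), a marker of immature B cells, was 1.75-fold lower at 490 against 855 CPM. Uchl1, Dusp5, Tyms and Atp1b1 were 3.19-fold, 3.16-fold, 2.00-fold and 1.98-fold lower, but in clusters 13 and 15 alone Dusp5 had a log2 ratio of -0.22 (-0.93 to 0.49) and Atp1b1 one of 0.31, and in clusters 2, 3 and 17 Tyms had one of -0.63 (-1.59 to 0.35).

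Jchain, which encodes the joining chain of secreted antibodies, was 117-fold higher in T2D B lineage cells with 3161 against 18 counts (log2 ratio 6.87). This rested on 7 T2D barcodes with at least 100 Jchain UMIs, while the 5 such control barcodes had been removed as doublets, and the ratio turned to -0.49 with doublets kept. It was -0.65 at 1000 UMIs and -0.62 at 500 UMIs. The interferon list had a median of 0.76 in B lineage cells (percentile 100), with 23 of 24 members higher. It was 0.49 in clusters 2, 3 and 17 and 0.75 in clusters 13 and 15, both at percentile 100. The immediate early list had a median of -0.43 (percentile 0.02), with 14 of 15 lower, led by Fos at 151 against 405 CPM. The inflammatory list had a median of 0.11 (percentile 93.8). Cell cycle genes had a median of -0.45 (percentile 0), with 34 of 35 lower, but -0.15 in clusters 2, 3 and 17 (percentile 17.2) and -0.17 in clusters 13 and 15 (percentile 5.95), both inside the central 95% of random lists. Nuclear oxidative phosphorylation genes had a median of -0.27 (percentile 0), with 83 of 85 lower. Unfolded protein response genes had a median of 0.26 (percentile 100), with Pdia4 and Xbp1 both at a log2 ratio of 0.75.

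Neutrophil transcripts were also present in B lineage cells, where the list of S100 and antimicrobial proteins had a median of -0.95 (percentile 0). In clusters 2, 3 and 17 S100a8 was 784 against 2236 CPM, beside 15308 and 39315 CPM in the free RNA of the same libraries. In T cells, 125 against 184, the same list had a median of -1.85 (percentile 0), with S100a8 at 536 against 3466 CPM. The B cell gene Cd79a was 82.5 against 26.3 CPM in T cells, below its free RNA levels of 243 and 203 CPM. From S100a8 and S100a9 the free RNA share of T cells was 3.47% in T2D and 9.57% in control. Free RNA at these shares does not account for the higher T2D level of Cd79a, whose source was not tested.

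T cells of the T2D library were higher in Txnip, which encodes a thioredoxin-binding regulator of glucose uptake, at 2.53-fold (437 against 173 CPM; log2 ratio 1.34, interval 1.08 to 1.60). The interleukin 7 receptor gene Il7r was 2.04-fold higher at 431 against 211 CPM, Tsc22d3 2.52-fold, and the natural killer receptor gene Klrb1c 2.34-fold. Bcl2l11, Nabp1, Id2 and Ahnak were 2.69-fold, 2.14-fold, 2.11-fold and 1.82-fold higher. Cd8b1, a chain of the CD8 co-receptor, was the only gene to meet the rule on the lower side, at 2.11-fold, and 10 cells held 77.0% of its T2D counts. The interferon list had a median of 0.35 in T cells (percentile 99.9), the immediate early list -0.36 (percentile 0.08), the inflammatory list -0.37 (percentile 0.615) and the cell cycle list -0.60 (percentile 0). With free RNA subtracted at the T cells' S100a8 and S100a9 share, these were 0.36, -0.19, -0.09 and -0.31, with the immediate early and inflammatory lists inside the central 95% of random lists. In dendritic cells the interferon list had a median of 1.13 (percentile 100), with Ly6a at 148 against 24.9 CPM and Oasl2 at 26.1 against 4.10 CPM.

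**Figure D4:**
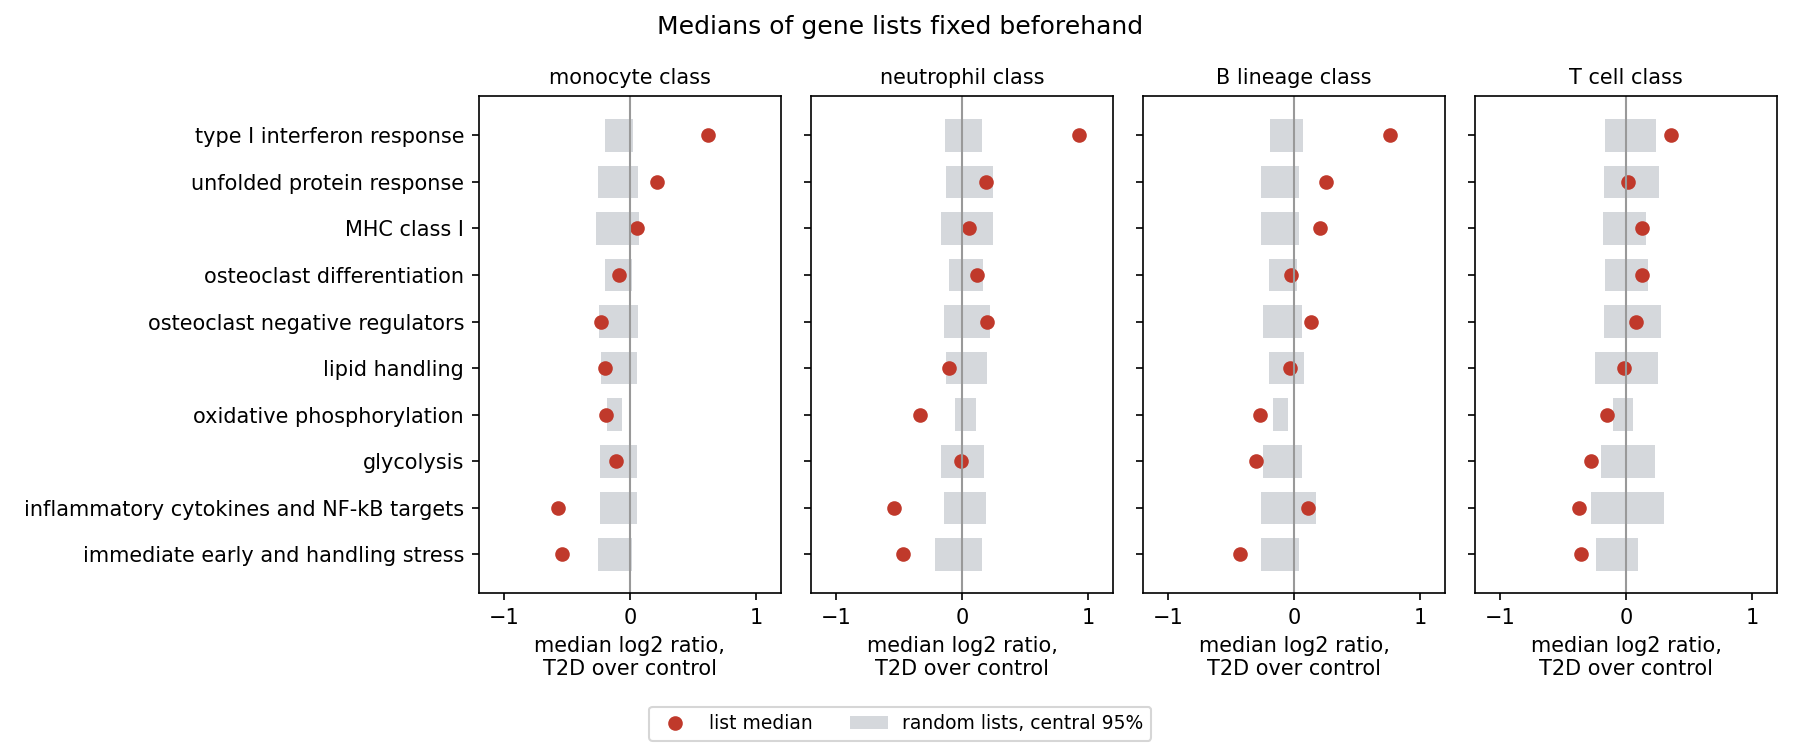
Median log2 ratio T2D over control (horizontal axis) of selected gene lists in monocytes, neutrophils, B lineage and T cells, 1 library per group, with the central 95% of 10000 random matched lists as grey bars. Neutrophils and B lineage cells pool clusters whose shares differ between the libraries. The interferon list lay at 0.62, 0.93, 0.76 and 0.35 in these classes, and the immediate early list at -0.54, -0.47, -0.43 and -0.36.

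Over all called cells of each library, which mixes composition with levels within classes, Vcan was 4.30-fold and Plin2 4.13-fold higher in T2D, at 190 against 44.3 CPM and 240 against 58.1 CPM. Ifi204, of a multigene family, was 2.52-fold, the B cell gene Ms4a1 2.30-fold, Gngt2 2.18-fold, Ddi2 2.09-fold and Ap2a2 2.04-fold higher. Jchain was 51.9-fold higher, a log2 ratio of 5.70 that was 0.43 with doublets kept and 1.39 at 1000 UMIs. Slc7a11 was 3.46-fold lower, the alarmin genes S100a8 and S100a9 were 1.95-fold and 1.83-fold lower, and Ifitm6, Fdps, the basophil protease gene Mcpt8 and Trem3 were 2.07-fold, 1.93-fold, 1.87-fold and 1.87-fold lower.

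Transcripts of mature osteoclasts were rare in both libraries. Ctsk had 8 counts in T2D and 20 in control, Ocstamp 37 and 7 (log2 ratio 2.73, 1.55 to 4.14), Atp6v0d2 9 and 10, and Oscar 1 and 1. Dcstamp and Calcr had 0 counts, with exact intervals up to 0.0643 CPM in T2D and 0.0512 CPM in control. Acp5 had 1241 and 843 counts (log2 ratio 0.89, 0.76 to 1.01) and Itgb3 351 and 870 (-0.98, -1.16 to -0.80). Tnfsf11, the gene for RANKL, had 2 and 4 counts. Tnfrsf11a had 129 and 111 (log2 ratio 0.55, 0.17 to 0.92), and Csf1r had a log2 ratio of 0.37 (0.32 to 0.43), both opposite in sign to their values within monocytes. Nfatc1 had one of 0.10 (0.01 to 0.19). Tnf was lower in T2D at 8.35 against 20.8 CPM (log2 ratio -1.31) and Il1b at 13.5 against 17.2 CPM (-0.35). C1qa, a macrophage gene, had 58 counts in T2D and 3 in control (log2 ratio 4.60, 2.98 to 6.92). Several of these genes lay below free RNA in both libraries: C1qa at 1.01 and 0.0416 CPM beside 5.12 and 3.26 CPM, Acp5 at 21.6 and 11.7 beside 26.2 and 20.1 CPM, Itgb3 at 6.12 and 12.1 beside 7.26 and 16.6 CPM, and Ctsk, Il1b, Tnfrsf11a and Csf1r likewise. The Y-linked gene Ddx3y was 29.0 and 27.1 CPM, and Xist had 3 and 4 counts.

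Depth and free RNA were measured in the same files. With each cell thinned to 500 UMIs the median number of genes was 299 in T2D and 305 in control. Monocytes differed more, at 318 against 335 genes, and immature neutrophils were at 191 and 188. The free RNA share of T and B lineage cells, from haemoglobin transcripts, was 1.76% in T2D and 1.82% in control. Estimates from S100a8 and S100a9, chosen after seeing the data, were 5.20% and 6.13% in clusters 2, 3 and 17 and 3.47% and 9.57% in T cells.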

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

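Of the tests in this part, the one on handling of the cell suspensions and the thinning of cells to 2191 UMIs were chosen only after the result was seen, as were the free RNA shares from S100a8 and S100a9.

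Some gene lists differed in direction between cell classes, and these differences were not tested. The MHC class II list had a median log2 ratio of -0.97 in monocytes, 0.76 in neutrophils, 0.11 in B lineage cells and 1.27 in T cells. Within the B lineage it was -0.07 in clusters 2, 3 and 17 (4 higher, 6 lower) and -0.52 in clusters 13 and 15 (8 of 9 lower), so the higher value arose only over the mixed class. The list of B cell development genes was also higher in T cells, at 0.91 (percentile 100, 10 of 12 higher), and in neutrophils, at 0.37 (percentile 99.4). The list of T cell naive and memory genes had -0.57 in monocytes and 0.12 in B lineage cells, but -0.01 in clusters 2, 3 and 17 and -0.04 in clusters 13 and 15. The classical macrophage activation list had -0.50 in monocytes and 0.21 in B lineage cells, with 0.03 in clusters 2, 3 and 17. The NADPH oxidase list had -0.31 in T cells and 0.10 in B lineage cells, with 0.03 in clusters 2, 3 and 17 and -0.19 in clusters 13 and 15.

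A signal also lay in barcodes below the cutoff, which the main comparisons did not use. In the 1330 T2D barcodes from 1000 UMIs to the cutoff of 2191, the B cell gene Cd79a stood at 1626 CPM, above 675 CPM in the 616 control barcodes of that range and above the free RNA levels of 243 and 203 CPM.

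The first pattern weighed is the immediate early list, lower in T2D monocytes by a median log2 ratio of -0.54. Free RNA is argued against, since the median stayed at -0.53 after subtraction at the S100a8 and S100a9 share and at -0.50 at that share of T cells, and so is depth, since monocytes of 6000 to 10000 UMIs, 647 T2D and 418 control cells, gave -0.64. In 8 of 9 cell classes the median lay below the central 95% of random lists, mature neutrophils being the exception, and in none above it, though that of T cells came inside it, at -0.19, once free RNA was subtracted at their share. A difference in how the cell suspensions were handled could give this and cannot be told apart from the groups, because each group was 1 library. The biological explanation, a difference between T2D and control marrow, stays open and untested.

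The second pattern is the split of monocytes by library, with 100% of them in clusters that took over 90% of their cells from 1 library. The planned test came out as the difference in UMIs per cell would predict, since with every cell thinned to 500 UMIs only 0.417% of monocytes lay in such clusters. That thinning also removes most information, so cells were afterwards thinned to 2191 UMIs, the deepest level all of them reach, where 89.4% stayed in such clusters, which argues against unequal depth as the whole cause, while 1000 UMIs gave 0.208%. Leaving the 47 immediate early and inflammatory genes out of the clustering left 99.8%. The excess of same-library cells among nearest neighbours was 1.66 times as high in monocytes as in immature neutrophils. The values were 44.97 against 27.08 percentage points, with clusters 2, 3 and 17 at 18.90. That ratio passed the limit set beforehand. It cannot exclude a shift common to all cells, because what such a shift gives in classes of unlike depth and spread was not measured. A shift common to all cells, a preparation effect particular to monocytes and a difference between T2D and control all remain possible and were not separated.

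The third pattern is the interferon list, higher in T2D monocytes by a median of 0.62. Free RNA is argued against by a median of 0.64 after subtraction at the S100a8 and S100a9 share and 0.59 at that share of T cells. A few strongly responding cells are argued against by 0.76, over 33 measured genes, without the 5% of each library's monocytes richest in the list. Leaving those cells out turned Ifit3 from -0.81 to 1.54, as its level fell from 6.04 to 2.54 CPM in T2D and from 10.6 to 0.874 CPM in control. Reads shared within gene families, or a strain variant in them, are argued against as the whole cause by 0.42 over the 16 remaining genes, whose random lists lay between -0.23 and 0.09. Whether the T2D model or the preparation gave the difference stays open, since both are the same split.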

How the results depend on the processing

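Values are log2 ratios of shares, medians of lists or log2 ratios of genes. The minimum of 500 UMIs, the S100a8 and S100a9 shares of free RNA, from clusters 2, 3 and 17 and from T cells, and the counting of cluster 11 with monocytes were chosen after seeing the data. Of 75 comparisons of shares 72 kept their direction, 50 of them within the counting interval. Of 94 for lists, free RNA and depth 93 kept it, all but the osteoclast list under TMM scaling, whose main median lay inside the random range. Of 1122 for named genes 1110 kept it. These totals include comparisons that leave a value as it was by construction. They are 7 shares without erythroid and megakaryocyte classes, absent from the main clustering, 7 list medians in 10 bins and 94 genes with at least 10 summed counts. Counting cluster 11 with monocytes likewise leaves other classes unchanged, and the 2 free RNA percentages have no direction to reverse. The totals thus overstate how many comparisons were open to change. The causes were not tested except where given.

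At 1000 UMIs mature neutrophils were -0.57, B lineage cells 0.96, granulocyte-monocyte progenitors -1.42, interferon 0.50 in monocytes and 0.93 in B lineage cells, inflammatory genes -0.79 and MHC class II -0.70 in monocytes. At 500 UMIs neutrophils were -0.25, mature neutrophils -0.58, monocytes with cycling monocytes 0.43, B lineage cells 1.10, progenitors -1.66, interferon 0.50, 1.12 and 0.93 in monocytes, neutrophils and B lineage cells and MHC class II -0.22. Jchain in B lineage cells reversed to -0.65 at 1000 UMIs, -0.62 at 500 UMIs and -0.49 with doublets kept, the last because control barcodes rich in it had been removed. With doublets kept mature neutrophils were -0.55, MHC class II -0.30 and interferon in B lineage cells 0.89. The Cell Ranger 2 cutoff, 4864 and 5639 UMIs, gave neutrophils -0.57, mature neutrophils -2.01, B lineage cells 1.09 and T cells -1.23. Mature neutrophils were -0.65 at 5% and -0.57 at 20% mitochondrial counts, progenitors -0.82 at 20%. At the Cell Ranger 2 cutoff, with doublets kept, at resolution 0.5 and with separate clustering, a cluster named immature neutrophil had more mature than immature markers among its leading genes, so the mature shares there are not those of 1 class.

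Resolution 0.5 gave mature neutrophils -0.48 and progenitors -0.97, and resolution 2 gave -0.43 and a reversed 0.29. Thinning to 500 UMIs gave -0.56 and -0.79. With separate clustering monocytes with cycling monocytes reversed to -0.97, as T2D clusters of 236, 685 and 285 cells stayed unnamed, and progenitors reversed to 0.43, with dendritic cells -0.61, interferon 0.47 and MHC class II -1.43 in monocytes. MHC class II in monocytes and interferon in B lineage cells were -0.61 and 0.89 with at least 10 summed counts, -1.24 and 0.61 with cells weighted equally, and -1.54 and 0.91 with free RNA subtracted at the S100a8 and S100a9 share. At that share of T cells interferon was 1.10 in neutrophils and 0.93 in B lineage cells. MHC class II was -0.45 with cluster 11 included. The T2D free RNA share was 1.27% from barcodes below 50 UMIs.

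The minimum of 300 UMIs was not run, since the plan left it out for a main minimum above 500 UMIs. T cells gave no share at resolution 0.5 or after thinning. No paired analysis was possible because each group has 1 library. Depth limits B lineage cells, whose median UMIs lie near the minimum, and T cells, where 46% of simulated 2-fold genes were recovered.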

Other observations

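Of the tests in this part, the one on Jchain was chosen only after the result was seen.

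Genes not described above also parted the libraries within the myeloid classes. In monocytes Cd38, an NAD-consuming ectoenzyme gene, was 42.2 CPM in T2D and 1.19 in control (log2 ratio 5.15, interval 4.25 to 6.22), and the chemoattractant receptor genes Fpr1 and C5ar1 had log2 ratios of 3.21 and 2.02. Wfdc21 was 358 against 49.1 CPM, and the T2D level of Lcn2, an iron-scavenging lipocalin gene, was 456 CPM against 232, although the S100 and antimicrobial list that holds both was lower (median -0.31, percentile 0.22, 11 of 16 members lower). Cycling monocytes had an unfolded protein response median of 0.52 (percentile 100), with the chaperone genes Hspa5 at 476 against 234 CPM and Calr at 521 against 258 CPM. They also had an immediate early median of -0.91 and an inflammatory median of -0.76, both at percentile 0.

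In mature neutrophils the cholesterol exporter gene Abca1 was 16.7 CPM in T2D and 1.10 in control, and Plin2 was 315 against 51.1 CPM, while the sterol synthesis gene Hmgcs1 was 6.46 against 23.0 CPM. Their interferon median was 1.09 (percentile 100), with Oasl1 at 22.6 against 1.72 CPM. In dendritic cells Apoe was 399 against 58.0 CPM and the Fc receptor gene Fcgr1 53.1 against 9.26 CPM. When the control library was clustered on its own, 40 control monocytes formed a cluster led by Ifit1, Slfn5 and Ifit3.

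A hypothesis from Fkbp5, Tsc22d3, Txnip and Ddit4 was that genes responsive to glucocorticoids were higher in T2D. Of 3 classes tested with other textbook members of that response, 1 had a median above the central 95% of random lists: monocytes at 0.37 (percentile 99.99, 10 genes). Neutrophils had -0.02 (percentile 35.8, 9 genes) and B lineage cells 0.20 (percentile 96.0, 8 genes, random lists up to 0.23). The prediction of a median above that range in all 3 classes was thereby not met, with B lineage cells missing it narrowly. With 8 to 10 genes per class this cannot exclude a weaker shared response. A response in monocytes alone may also hold and is a hypothesis.

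The high Jchain level in T2D B lineage cells may reflect doublet removal in the control library. With doublets kept its log2 ratio was -0.49 in place of 6.87, since 3014 Jchain UMIs of the control library lay in 5 barcodes that Scrublet had marked, against 102 UMIs in 1 such T2D barcode.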
